A study of Homo sapiens with 8 samples.

How the data were processed

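The data are 8 arrays of the Affymetrix Human Exon design, 2 for each combination of control or BTG1 shRNA with vehicle or prednisolone for 8 h, in cells labelled RS4;11. Total RNA was labelled with biotin, and probes were summarised over the core meta-probe sets of files built on hg18, per the labels. Robust multi-array averaging (RMA) and Partek are named per the submitters' processing notes. Their versions and settings are not given in the sources used here.

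The deposited table holds log2 expression values per transcript cluster with most decimal points lost. Of 143048 values 153 kept a point, and these lay between 2.47 and 12.25. The point was put back after the first digit, or after the second digit where the value started with 1, which applied to 2831 values. Of values without a point, 0 started with 14 to 19. The highest restored value, 13.4, follows from the rule and is no check on it. The correlation between arrays was 0.446 to 0.587 for the table as deposited and 0.872 to 0.995 after the points were put back. The unit therefore differed from the plain log2 table assumed when the tests were chosen, but the tests stayed as planned on the restored log2 values. No other normalization was applied. All 17881 clusters were tested and no filter on low values was used, and 0 columns of the table were left out.

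Gene symbols came from the platform annotation: 14432 clusters had 1 symbol, 2408 several and 1041 none, and 0 symbols changed when updated through the gene identifier. Genes were named only from clusters with 1 symbol, except for BTG1, FKBP5 and PRMT1, whose clusters carry a second symbol that is given with them. BTG2 was to be reported but has no cluster in that annotation. Genomic positions were not used here.

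A linear model with 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 3.51 prior degrees of freedom), so that all groups shared an estimate of the spread. There were 7 contrasts: prednisolone against vehicle within each shRNA, BTG1 shRNA against control shRNA within each treatment, the difference of the prednisolone effects, and both main effects averaged. P-values were adjusted by Benjamini-Hochberg over all clusters of a contrast, with a threshold of 0.05. The 2-fold selection named in the series' design was counted without a test. The relative size of the response was the least-squares slope through the origin over clusters called and over 2-fold in the averaged prednisolone contrast.

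For each contrast the named genes are the 12 with the largest rise and the 12 with the largest fall among clusters with 1 symbol, adjusted p below 0.05 and no overlap between the arrays compared. For the difference of effects, the same sign in both same-numbered pairs replaced the last condition. Where fewer than 6 passed in a direction, the smallest p-values filled it up to 6. NR3C1, BTG1, PRMT1, FKBP5, TSC22D3, BCL2L11, BCL2 and MYC are always given, and up to 4 members per list with the smallest p serve as examples. The groups, contrasts, gene lists, naming rule and alternative settings were fixed before the data were examined.

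There were 29 gene lists, of which 28 with at least 5 measured members were tested in 5 contrasts, using the cluster with the highest mean per gene. They covered glucocorticoid-induced genes (general and lymphoid), the receptor with its chaperones and coregulators, the BTG/TOB family with the CCR4-NOT deadenylase, pro- and anti-apoptotic BCL2 relatives, G1/S, G2/M, MYC and ribosome biogenesis, glycolysis, oxidative phosphorylation and cholesterol synthesis. Others held amino acid response, unfolded protein response, heat shock, interferon, NF-kB, immediate early, p53 and FOXO genes, B-lineage, MLL-fusion and antigen presentation genes, RNA interference genes and histones. Markers of T cells, myeloid cells, erythroid cells with platelets, and stromal with epithelial cells completed them. Some lists share genes, so their results are not independent. TXNIP is in both glucocorticoid lists and the FOXO list, and SESN1 is in the FOXO and p53 lists. Lists were tested with camera (preset correlation 0.01, which compares a list with other genes), again with an estimated correlation, and with fry (which tests whether the list moves one way). With an estimated correlation, camera rests on the 4 residual degrees of freedom. A call lost there therefore does not by itself show correlation between the genes. For FOXO targets with prednisolone in control cells the estimate was -0.048, below the preset, yet the camera adjusted p rose from 7.52e-06 to 0.0614.

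The scripts were tested on simulated data for the 17881 clusters with 200 changed. For changes of 1, 2 and 4 on the log2 scale, 16%, 68% and 98% were recovered in the control prednisolone contrast, 30%, 66% and 98% in the contrast on the arrays labelled BTG1 shRNA, and 18%, 86% and 96% for the shRNA contrast under vehicle. The difference of effects recovered 0%, 42% and 84%. All these shares hold for 200 changed clusters and would be lower with fewer, where the adjusted cutoff is stricter. At most 3 unchanged clusters were called. The simulated list shift was found with 0 false calls among 28 lists, and a slope of 0.5 was recovered as 0.491 over 122 clusters. The simulated noise was independent between clusters, so false list calls among correlated genes were not checked. In the data the estimated correlation was 0.35 for G2/M genes and 0.71 for histones.

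Alternatives were the replicate number as a block, quantile normalization, centring on array medians, leaving out the 30% dimmest clusters or those without a symbol, an intensity trend with and without a robust prior, array weights, fits on the compared arrays only, an adjusted p of 0.01, a 1.5-fold threshold, other selections for the slope, other list tests, and each array left out in turn. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the other groups. If that group is outside the contrast, the effect is unchanged and only the spread estimate and its degrees of freedom change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.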

Results

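Gene expression was measured on 8 Affymetrix exon arrays of cells labelled as RS4;11, a B-cell precursor acute lymphoblastic leukemia line that carries an MLL fusion. The cells carried a control shRNA or an shRNA against BTG1, a member of the BTG/TOB family of antiproliferative proteins, and were exposed for 8 h to vehicle or to prednisolone, a synthetic glucocorticoid. Each of the 4 groups held 2 arrays. The design addresses how loss of BTG1 alters the transcriptional response to prednisolone, including that of NR3C1, which encodes the glucocorticoid receptor. No label says whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Values are log2 expression levels of 17881 transcript clusters. The median absolute difference between replicate arrays was 0.44 for control shRNA with vehicle, 0.21 for control shRNA with prednisolone, 0.18 for BTG1 shRNA with vehicle and 0.25 for BTG1 shRNA with prednisolone. The first control vehicle array had the narrowest distribution, with an interquartile range of 2.95 against 3.39 to 3.80 on the other arrays. Precision is limited by the number of arrays.

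The targeted gene was examined first. Its only cluster, 3465409, is annotated BTG1;LINC01619 and so covers both genes. It read 9.34 and 9.36 on the control vehicle arrays, 10.51 and 10.7 on the control prednisolone arrays. It read 7.15 and 7.42 on the BTG1 shRNA vehicle arrays, and 8.14 and 7.80 on the BTG1 shRNA prednisolone arrays. The level was lower with BTG1 shRNA by -2.06 (SE 0.20, 4.18-fold, limma adjusted p = 0.000388) under vehicle and by -2.64 (SE 0.20, 6.23-fold, adjusted p = 0.000107) under prednisolone, with no overlap between arrays. NR3C1 (cluster 2879312) was also lower on the arrays labelled BTG1 shRNA, by -2.53 (SE 0.28, adjusted p = 0.000733) under vehicle and -3.51 (SE 0.28, adjusted p = 0.000133) under prednisolone. CD3D, CD3E and CD3G, subunits of the T-cell receptor complex, lay at or above the 99.0th percentile of every array labelled BTG1 shRNA and at or below the 34.7th percentile of every control array. These arrays are therefore called the arrays labelled BTG1 shRNA throughout. The shRNA and the lineage difference coincide in every comparison between them and the control arrays.

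**Figure D1:**
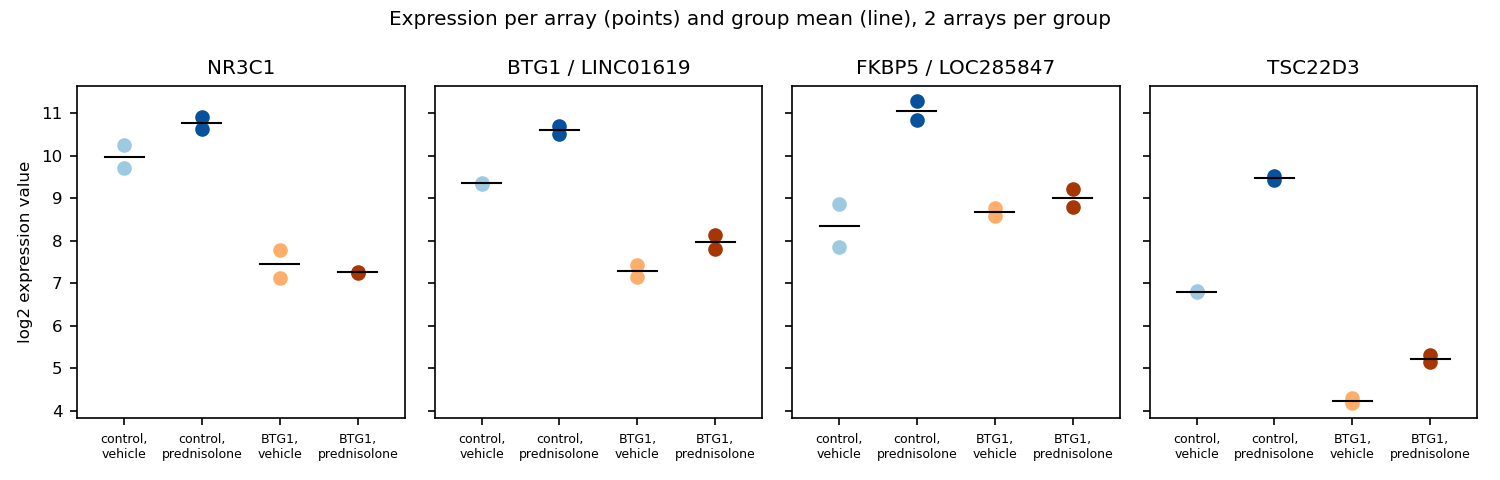
Log2 expression value (vertical axis) of NR3C1, the BTG1 / LINC01619 cluster, the FKBP5 / LOC285847 cluster and TSC22D3 in the 4 groups (horizontal axis); points are single arrays and lines are means of 2 arrays. NR3C1 lies at 7.45 and 7.25 in the groups labelled BTG1 shRNA, against 9.98 and 10.77 in the control shRNA groups.

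Under vehicle, the arrays labelled BTG1 shRNA carried a T-lineage profile and lacked much of the B-lineage profile of the control arrays. CD3G was higher by 8.12 (SE 0.25), CD3D by 8.10 (SE 0.17) and CD3E by 6.90 (SE 0.30). Also higher were SH2D1A, which encodes the adaptor SAP of T and NK cells (6.35), TRAT1, a T-cell receptor associated adaptor (5.97), TOX, a regulator of T-cell development (5.69), and the tetraspanin TSPAN7 (8.37). All of these were dim on the control arrays, the CD3 genes at or below the 34.7th percentile, so their level above background there is unknown and the rises are not ranked. Among 11 measured T-cell markers 8 were higher and 0 lower (8 and 0 adjusted over the list alone). The median was 2.56 (camera adjusted p = 7.57e-08, adjusted p = 0.401 with an estimated correlation). B-lineage genes were lower in 19 of 21 cases (19 adjusted over the list alone, median -3.84, camera adjusted p = 1.23e-17, adjusted p = 0.242 with an estimated correlation). Among them were the signalling subunit CD79A (-5.03, SE 0.17), the transcription factor EBF1 (-5.93, SE 0.21), CD9 (-6.58, SE 0.18) and the interleukin-7 receptor IL7R (-7.04, SE 0.26). Genes linked to MLL fusions were lower in 9 of 11 cases (10 adjusted over the list alone, median -1.89, camera adjusted p = 5.96e-08, adjusted p = 0.401 with an estimated correlation). They included FLT3 (-7.04, SE 0.25), PROM1 (-6.89, SE 0.32), MEF2C (-6.29, SE 0.22) and MEIS1 (-4.28, SE 0.36). Of 12 antigen presentation genes 8 were lower (8 adjusted over the list alone, median -2.27, camera adjusted p = 1.59e-08, adjusted p = 0.242 with an estimated correlation). They included the invariant chain CD74 (-7.56, SE 0.20), HLA-DRA (-6.56, SE 0.22) and HLA-DPA1 (-6.41, SE 0.20). Fry, which does not compare a list with other genes, gave adjusted p = 0.000379 for T-cell markers and 0.000946 for MLL-fusion genes. For B-lineage and antigen presentation genes it gave 7.34e-05 each. On the arrays labelled BTG1 shRNA, IL7R, FLT3, PROM1, CD74, HLA-DRA and HLA-DPA1 were dim, with HLA-DRA at or below the 14.1th percentile. Their level above background there is unknown, so the sizes of these falls are uncertain. HLA genes have close homologues whose probes can cross-hybridise, so single HLA values are uncertain.

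Interferon response genes were lower as a group (6 of 20 lower and 1 higher, 9 and 2 adjusted over the list alone, median -0.61, camera adjusted p = 0.0168, adjusted p = 0.296 with an estimated correlation). OAS2 was at -4.29 (SE 0.31) and IFIT3 at -1.77 (SE 0.18), both dim on the arrays labelled BTG1 shRNA. This call ended without the second control vehicle array (adjusted p = 0.0678). Among genes of glucocorticoid action, TSC22D3, which encodes the glucocorticoid-induced leucine zipper GILZ, was lower by -2.57 (SE 0.17, adjusted p = 6.51e-05) and BCL2, an inhibitor of apoptosis, by -2.21 (SE 0.29, adjusted p = 0.00182). ZBTB16 was higher by 2.96 (SE 0.30, adjusted p = 0.000536). In the general glucocorticoid list 7 of 22 genes were lower and 1 higher (8 and 3 adjusted over the list alone, median -0.41), with a camera adjusted p of 0.0587 and a fry adjusted p of 0.00941. In the lymphoid list 6 of 21 were lower and 3 higher (6 and 5 adjusted over the list alone, median -0.37), with a camera adjusted p of 0.451 and a fry adjusted p of 0.0059. MYC differed by 0.28 (SE 0.19, adjusted p = 0.348), and BCL2L11 by 0.32 (SE 0.22, adjusted p = 0.355). The cluster of FKBP5 and LOC285847 differed by 0.32 (SE 0.35, adjusted p = 0.516) and the cluster of PRMT1 and ADM5 by 0.22 (SE 0.25, adjusted p = 0.547). In all, 1512 clusters were higher and 1111 lower at adjusted p below 0.05, and 66 were higher and 82 lower by over 16-fold, where dim values on either side make the size uncertain. The median over all clusters was -0.15 as deposited and -0.04 after quantile normalization, so small negative differences should be read against that shift. Without the second control vehicle array the count was 5958 and the balance turned, with 2482 higher and 3476 lower. Without the first or second vehicle array labelled BTG1 shRNA it was 1492 or 1289.

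**Figure D2:**
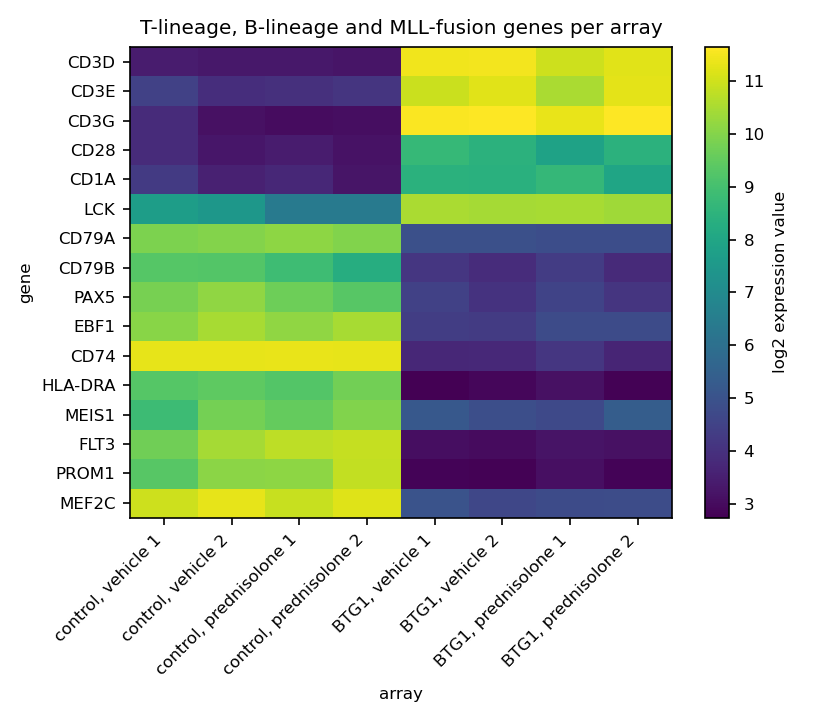
Log2 expression value (colour) of 16 lineage genes (vertical axis) on the 8 arrays (horizontal axis). CD3D, CD3E and CD3G lie at or above the 99.0th percentile on the 4 arrays labelled BTG1 shRNA, where the B-lineage gene CD79A, at 4.83 to 4.92, stays below its control values of 9.89 to 10.15.

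Under prednisolone the lineage contrast stood again. CD3G was higher by 8.44 (SE 0.25), CD3D by 7.83 (SE 0.17) and TSPAN7 by 8.53 (SE 0.27). FLT3 was lower by -7.63 (SE 0.25), CD74 by -7.42 (SE 0.20) and PROM1 by -7.53 (SE 0.32). The dimmer side of these differences is again of unknown level above background. Of 11 T-cell markers 8 were higher (8 adjusted over the list alone, camera adjusted p = 9.73e-09, adjusted p = 0.194 with an estimated correlation). Of 21 B-lineage genes 16 were lower (18 and 1 higher adjusted over the list alone, camera adjusted p = 3.07e-18, adjusted p = 0.0768 with an estimated correlation). Of 11 MLL-fusion genes 10 were lower (11 adjusted over the list alone, camera adjusted p = 1.68e-12, adjusted p = 0.107 with an estimated correlation). Of 12 antigen presentation genes 10 were lower (11 adjusted over the list alone, camera adjusted p = 3e-12, adjusted p = 0.0768 with an estimated correlation).

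Among genes of glucocorticoid action, TSC22D3 was lower by -4.25 (SE 0.17), SGK1 by -4.72 (SE 0.23), GSDME by -4.44 (SE 0.26), P2RY14 by -4.26 (SE 0.25) and the cluster of FKBP5 and LOC285847 by -2.04 (SE 0.35). In the lymphoid glucocorticoid list 12 of 21 genes were lower and 2 higher (14 and 3 adjusted over the list alone, camera adjusted p = 8.56e-09, adjusted p = 0.0768 with an estimated correlation). In the general list 12 of 22 were lower and 2 higher (13 and 3 adjusted over the list alone, camera adjusted p = 5.57e-07, adjusted p = 0.107 with an estimated correlation). Cholesterol synthesis genes were higher in 8 of 15 cases (9 adjusted over the list alone, camera adjusted p = 4.8e-05, adjusted p = 0.0768 with an estimated correlation), led by DHCR7 (4.20, SE 0.21), LSS (2.59, SE 0.18) and MVD (2.63, SE 0.26). Glycolysis genes were higher in 6 of 19 cases with 1 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.00707, adjusted p = 0.25 with an estimated correlation), with ENO2 at 4.95 (SE 0.25) and PFKM at -3.57 (SE 0.22). MYC was higher by 0.93 (SE 0.19, adjusted p = 0.0137) and the MYC and ribosome biogenesis list with it (5 of 14, 6 adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.292 with an estimated correlation). FOXO targets were lower as a group (6 of 14 lower and 2 higher, 8 and 2 adjusted over the list alone, camera adjusted p = 0.000244, adjusted p = 0.0768 with an estimated correlation). Interferon response genes were lower (9 of 20 lower and 1 higher, 9 and 3 adjusted over the list alone, camera adjusted p = 0.00416, adjusted p = 0.107 with an estimated correlation). So were histone genes (6 of 21, 7 adjusted over the list alone, camera adjusted p = 2.17e-05, adjusted p = 0.475 with an estimated correlation). G2/M genes had a median of -0.64 with 1 of 18 lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.00309, adjusted p = 0.475 with an estimated correlation). Singly, MYC and CNOT6L missed the threshold without any 1 of the 4 prednisolone arrays (adjusted p = 0.0528 to 0.184).

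Camera called 14 lists here, and 0 of them held with an estimated correlation. That test rests on the 4 residual degrees of freedom, so the lost calls do not show an effect of correlation between genes. Fry, which does not compare a list with other genes, called 12 lists. The BTG/TOB and CCR4-NOT deadenylase list was called lower on the strength of a few members (4 of 14 lower and 6 positive, 5 lower adjusted over the list alone, median -0.11, mean -0.50, camera adjusted p = 0.0306, adjusted p = 0.475 with an estimated correlation), with PAN3 at -3.05 (SE 0.32) and CNOT6L at -0.87 (SE 0.21). That call and the G2/M call ended without the first prednisolone array labelled BTG1 shRNA (adjusted p = 0.0753 for each). The BTG/TOB call also ended without the second control prednisolone array (adjusted p = 0.263). At adjusted p below 0.05, 1791 clusters were higher and 1343 lower. Of the clusters called under both treatments 1857 of 1872 differed in the same direction, in comparisons that shared no array. The count was 1746 without the second control prednisolone array and 1934 or 2066 without the first or second prednisolone array labelled BTG1 shRNA. Centring each array moved the median over all clusters from 0.04 to -0.09.

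In control shRNA cells, prednisolone raised genes of glucocorticoid action strongly. SGK1, a serine/threonine kinase and glucocorticoid target, rose by 4.64 (SE 0.23, limma adjusted p = 0.000567), from 4.13 ± 0.10 to 8.77 ± 0.42 (SD, n = 2 arrays each). P2RY14, a nucleotide sugar receptor, rose by 4.08 (SE 0.25). Both were dim on the vehicle arrays, P2RY14 at 3.04, so their level above background there is unknown and no fold is given. The cluster of FKBP5 and LOC285847, of which FKBP5 encodes a co-chaperone of the receptor, rose by 2.70 (SE 0.35, adjusted p = 0.0134). TSC22D3 rose by 2.67 (SE 0.17, adjusted p = 0.00118) and the BTG1 and LINC01619 cluster by 1.26 (SE 0.20, adjusted p = 0.0288). NR3C1 itself stood at 0.79 (SE 0.28, 1.73-fold) and did not pass (adjusted p = 0.269), with no overlap between the 9.98 ± 0.37 of the vehicle arrays and the 10.77 ± 0.19 of the prednisolone arrays (SD of 2 arrays each).

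Among clusters with 1 gene symbol, other large rises were RASSF4 (3.74), OGFRL1 (3.66), NDRG2 (3.51), IL6ST, the shared signalling subunit of the interleukin-6 receptor family (3.36), and PIK3IP1, an inhibitor of PI3-kinase (3.19). They also included LONRF1 (3.13), MAP3K5, the stress kinase ASK1 (3.12), GSDME, a gasdermin that caspase-3 cleaves (3.12), SLA, an adaptor that damps antigen receptor signalling (3.10), and SHISA2 (3.07). Large falls were those of PRICKLE1, a planar cell polarity gene (-3.46, SE 0.16), IL1B, which encodes interleukin-1 beta (-3.19, adjusted p = 0.00139), the urokinase receptor PLAUR (-2.19), the growth factor receptor PDGFRB (-2.09), and GLDC of glycine cleavage (-2.07). Others were the inhibitor of DNA binding ID3 (-2.04), CD180 (-2.01), KANK2 (-2.00), TFAP4 (-1.98), ENTPD1-AS1 (-1.97), CSPG4 (-1.93) and GNAZ (-1.91). Of genes fixed in advance, BCL2L11, which encodes the pro-apoptotic protein BIM, stood at 1.20 (SE 0.22, adjusted p = 0.0539) and BCL2 at -0.81 (SE 0.29, adjusted p = 0.281). MYC was at -0.78 (SE 0.19, adjusted p = 0.121) and the cluster of PRMT1 and ADM5 at -0.64 (SE 0.25, adjusted p = 0.319). In total 166 clusters rose and 105 fell at adjusted p below 0.05. By over 2-fold, the selection stated in the series' design, 691 were higher and 249 lower. The median over all clusters was -0.16, which quantile normalization moved to -0.05. Leaving out an array labelled BTG1 shRNA cannot change an effect in this contrast. It changes only the spread estimate and its degrees of freedom. The count of 271 called clusters became 163 without the first control vehicle array, 770 without the second, and 145 (121 up and 24 down) and 40 (36 and 4) without the first and second control prednisolone arrays. It was 129 (93 and 36) without either vehicle array labelled BTG1 shRNA and 144 (105 and 39) without either prednisolone array so labelled. The BTG1 and LINC01619 call was lost in each of these (adjusted p = 0.0548 to 0.3) except without the second control vehicle array, and also after quantile normalization. Counts over 2-fold were 584 (329 up and 255 down) and 2672 (1702 and 970) without the first and second control vehicle arrays. They were 1784 (1358 and 426) and 556 (351 and 205) without the first and second control prednisolone arrays, so the upward balance was much smaller without the first vehicle array. Without the second control prednisolone array the FKBP5 cluster, OGFRL1, IL6ST, LONRF1 and all listed falls but PRICKLE1, IL1B and PLAUR also missed the threshold (adjusted p = 0.06 to 0.304). LONRF1, GLDC, CD180 and CSPG4 missed it as well without the first control prednisolone array (adjusted p = 0.0519 to 0.102), CSPG4 without either control vehicle array and CD180 without any array labelled BTG1 shRNA (adjusted p = 0.0531 to 0.0949).

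Among the gene lists, 14 of the 21 measured genes of the lymphoid glucocorticoid list rose when adjusted over the list alone (8 over all genes, 0 fell, median 1.16, camera adjusted p = 1.77e-17). This call held with an estimated correlation (adjusted p = 0.0313). The general glucocorticoid list followed with 8 of 22 (10 adjusted over the list alone, median 0.65, camera adjusted p = 1.96e-10, adjusted p = 0.0967 with an estimated correlation). It included NFKBIA, the inhibitor of NF-kB (2.04, SE 0.18), and the clock gene PER1 (1.80, SE 0.19). Amino acid response genes rose (3 of 16, 4 adjusted over the list alone, camera adjusted p = 2.25e-07, adjusted p = 0.0614 with an estimated correlation). The cystine transporter SLC7A11 rose by 2.99 (SE 0.38), DDIT3 by 1.77 (SE 0.19) and SESN2 by 1.17 (SE 0.18). FOXO targets rose (4 of 14, 5 adjusted over the list alone with 1 lower, camera adjusted p = 7.52e-06, adjusted p = 0.0614 with an estimated correlation). SESN1 rose by 2.70 (SE 0.33), TXNIP by 2.00 (SE 0.22) and SESN3 by 1.36 (SE 0.24). MYC and ribosome biogenesis genes fell (2 of 14, 7 adjusted over the list alone, median -0.81, camera adjusted p = 0.000294, adjusted p = 0.327 with an estimated correlation). RRP9 was at -1.08 (SE 0.18) and RRP12 at -1.11 (SE 0.20). The list call ended without the second control vehicle array (adjusted p = 0.159). Singly, RRP9, RRP12, SESN2 and SESN3 missed the threshold without most of the arrays in turn (adjusted p = 0.0503 to 0.409), and PER1, DDIT3, SLC7A11, SESN1 and TXNIP without the second control prednisolone array (adjusted p = 0.0535 to 0.0828). SLC7A11 missed it as well without the first control vehicle array (adjusted p = 0.0512).

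Smaller shifts were called for 5 lists that were all lost with an estimated correlation. G2/M genes had a median of 0.42 with 0 of 18 passing singly and 0 adjusted over the list alone (camera adjusted p = 0.00569, adjusted p = 0.73 with an estimated correlation). Histone genes had a median of 0.27 with 0 of 21 and 0 (0.00153, adjusted p = 0.756 with an estimated correlation). MLL-fusion genes had a median of 0.43 with RUNX2 alone rising among 11 by 1.06, SE 0.18, and 2 adjusted over the list alone (0.000891, adjusted p = 0.607 with an estimated correlation). The p53 targets had a median of 0.07 and 10 positive, with SESN1 and TP53INP1 (1.49, SE 0.20) rising among 17, 2 higher and 1 lower adjusted over the list alone (0.0453, adjusted p = 0.327 with an estimated correlation). Myeloid markers had a median of -0.36 with 0 of 14 passing and 1 lower adjusted over the list alone (0.0453, adjusted p = 0.756 with an estimated correlation). In limma 0 members of the G2/M, histone and myeloid lists passed, within a comparison where 2526 clusters had unadjusted p below 0.05. Without the first control vehicle array the MLL-fusion, G2/M, p53 and myeloid calls ended (adjusted p = 0.0988, 0.788, 0.129 and 0.36). The myeloid call also ended without the second control prednisolone array (adjusted p = 0.163). The p53 call ended without the second control vehicle array (adjusted p = 0.0663) or the first control prednisolone array (adjusted p = 0.0568). RUNX2 singly missed the threshold without any array but the second control vehicle array (adjusted p = 0.0898 to 0.386), TP53INP1 without either control prednisolone array (adjusted p = 0.0804 and 0.147) and SESN1 without the second of these (adjusted p = 0.0694). Quantile normalization ended the G2/M, p53 and myeloid calls (adjusted p = 0.142, 0.0781 and 0.0781).

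On the arrays labelled BTG1 shRNA, where CD3D, CD3E and CD3G stood at or above the 99.0th percentile, prednisolone changed 0 clusters at adjusted p below 0.05 in limma. There were 186 at unadjusted p below 0.05 against 894 expected by chance, with a smallest adjusted p of 0.999965. The spread was shared by all groups, and replicates differed more for control vehicle (median 0.44) than here (0.18 with vehicle, 0.25 with prednisolone). A count below chance may reflect this shared spread, so 0 calls do not show that no cluster responded. The fit on these arrays alone also called 0. Of the genes fixed in advance, NR3C1 stood at -0.20 (SE 0.28), the BTG1 and LINC01619 cluster at 0.68 (SE 0.20), TSC22D3 at 0.99 (SE 0.17) and the cluster of FKBP5 and LOC285847 at 0.34 (SE 0.35). BCL2L11 stood at 0.18 (SE 0.22), BCL2 at -0.14 (SE 0.29), MYC at -0.13 (SE 0.19) and the cluster of PRMT1 and ADM5 at -0.35 (SE 0.25). Differences over 2-fold were seen for 25 clusters upward and 13 downward. This balance turned at 1.5-fold, with 134 upward and 236 downward. The count of 38 was 75 without the first vehicle array (45 upward and 30 downward). The balance also turned without the second vehicle array, with 75 (32 upward and 43 downward), and without the second prednisolone array, with 280 (79 upward and 201 downward). The smallest p-values belonged to SLC7A11 (2.73, SE 0.38), ACSS2, an acetyl-CoA synthetase (1.31, SE 0.19), VEGFA (1.42, SE 0.21), LSS (1.11, SE 0.18), TSC22D3 and MVD (1.40, SE 0.26) upward. Downward they belonged to PRR3 (-0.89), OGN (-0.71), SVBP (-1.19), CMAHP (-0.95), PTPN6 (-0.60) and GZMA (-0.95). In the simulated test at this array number, which used the same shared spread, 66% of changes of 2 on the log2 scale were called. That simulation had 200 changed clusters, which loosens the Benjamini-Hochberg cutoff. Where few clusters change, a smaller share would be called, so the 66% does not make the 0 calls informative. SLC7A11, at 2.73, was not called here.

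As a group, cholesterol synthesis genes rose on these arrays (0 of 15 singly, 6 adjusted over the list alone, 14 positive, median 0.64, camera adjusted p = 1.46e-20). The smallest p-values were those of LSS, MVD, MVK (1.21, SE 0.23) and INSIG1 (0.91, SE 0.23). Amino acid response genes rose as well (0 of 16 singly, 5 adjusted over the list alone, 16 positive, median 0.53, camera adjusted p = 8.18e-19). They included SLC7A11, VLDLR (1.23, SE 0.23), SLC7A5 (0.78, SE 0.21) and SESN2 (0.61, SE 0.18). Both calls held with an estimated correlation (adjusted p = 0.0105 for each). The general and lymphoid glucocorticoid lists had medians of 0.19 and 0.16, with 1 member higher in each adjusted over the list alone (camera adjusted p = 6.74e-05 and 0.00355, adjusted p = 0.328 for each with an estimated correlation). The lymphoid call ended without the second vehicle array (adjusted p = 0.134) or the second prednisolone array (adjusted p = 0.0582).

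Lower on balance on these arrays, each with 0 members passing singly or adjusted over the list alone, were histones (median -0.46), G2/M (-0.35), G1/S and DNA replication (-0.26), and MYC and ribosome biogenesis (-0.19). So were glucocorticoid receptor, chaperone and coregulator genes (-0.20), RNA interference genes (-0.14) and T-cell markers (-0.12). Antigen presentation genes were higher on balance (median 0.16, 0 singly and 0 adjusted over the list alone). The camera adjusted p was 5.17e-11, 1.45e-08, 8.26e-05, 0.000557, 0.00344, 0.0358, 0.0227 and 0.0445 in that order. With an estimated correlation the adjusted p was 0.39, 0.328, 0.328, 0.328, 0.525, 0.566, 0.566 and 0.525. The histone and RNA interference lists leaned up without the first prednisolone array (adjusted p = 0.0868 and 0.849), without which the receptor and T-cell calls ended too (adjusted p = 0.426 and 0.581). Without the second vehicle array the receptor, G1/S, MYC and RNA interference calls ended (adjusted p = 0.289, 0.151, 0.158 and 0.207), and without the first the T-cell call (adjusted p = 0.172). The antigen presentation call ended without any 1 of the 8 arrays (adjusted p = 0.0543 to 0.247). Quantile normalization ended the receptor, MYC, RNA interference and antigen presentation calls (adjusted p = 0.224, 0.0547, 0.547 and 0.0679).

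The difference of the prednisolone effect between the arrays labelled BTG1 shRNA and the control arrays was tested directly. It passed for 24 clusters, 5 higher and 19 lower, with 1664 at unadjusted p below 0.05. SGK1 differed by -4.42 (SE 0.33, adjusted p = 0.00862), from a rise of 4.64 in control cells against 0.22 on the arrays labelled BTG1 shRNA. P2RY14 (-3.92), RASSF4 (-3.90), SLA (-3.76), NDRG2 (-3.52), GSDME (-3.02), CEMIP2 (-2.89), RIN2 (-2.84), SMIM3 (-2.77), TXNIP (-2.56), PIK3IP1 (-2.46) and WDR91 (-2.36) likewise responded less. So did NFKBIA (-2.08, adjusted p = 0.0441). Of genes with a fall in control cells, the difference passed for IL1B (3.41), PRICKLE1 (3.38), PDGFRB (2.36), PLAUR (2.24) and GNAZ (2.23). IL1B, PRICKLE1 and PDGFRB were already dim on the vehicle arrays labelled BTG1 shRNA (3.23, 3.53 and 4.07), below their control level with prednisolone (4.97, 3.88 and 4.54). A fall might not be measurable there, so these 3 differences do not show a lost response. TRIB1 came next without passing (2.03, adjusted p = 0.0659). The NR3C1 response differed by -0.99 (SE 0.39) and did not pass (adjusted p = 0.532). The differences for TSC22D3 (-1.68, SE 0.24, adjusted p = 0.0705), the FKBP5 cluster (-2.36, SE 0.49, adjusted p = 0.193), BCL2L11 (-1.02, adjusted p = 0.437), the BTG1 cluster (-0.58, adjusted p = 0.537), BCL2 (0.66, adjusted p = 0.546), MYC (0.65, adjusted p = 0.536) and the PRMT1 cluster (0.29, adjusted p = 0.638) did not pass either. The median over all clusters was 0.20, which quantile normalization moved to 0.06. After that step 12 clusters were higher and 24 lower. Without the second control prednisolone array, or without any single array labelled BTG1 shRNA, 0 clusters passed. There were 15 without the second control vehicle array and 7 without the first control prednisolone array.

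Of the gene lists, 8 differed in their prednisolone effect with the preset correlation and 0 with an estimated one. Fry, which does not compare a list with other genes, called 4 of these 8. Its adjusted p was 0.0055 for the lymphoid and 0.0432 for the general glucocorticoid list, 0.0201 for FOXO targets and 0.0308 for cholesterol synthesis. Lower on the arrays labelled BTG1 shRNA were the lymphoid glucocorticoid list (4 of 21, 11 adjusted over the list alone with 1 higher, median -1.02, camera adjusted p = 2.48e-11, adjusted p = 0.0714 with an estimated correlation) and the general list (3 of 22, 8 adjusted over the list alone, 9 positive, median -0.53, 3.37e-06, adjusted p = 0.241 with an estimated correlation). FOXO targets were lower too (2 of 14, 4 adjusted over the list alone with 1 higher, median -0.32, 0.0006, adjusted p = 0.142 with an estimated correlation). TXNIP belongs to both glucocorticoid lists and to the FOXO list, so these calls are not separate evidence. Cholesterol synthesis genes were higher (0 of 15, 5 adjusted over the list alone, median 0.81, 0.000201, adjusted p = 0.142 with an estimated correlation), with LSS at 1.72 and DHCR7 at 1.54. This call ended without the second control vehicle array (adjusted p = 0.117). Amino acid response genes had a median difference of 0.03 with 8 of 16 positive (1 lower adjusted over the list alone, camera adjusted p = 0.482), from medians of 0.55 in control cells and 0.53 on the arrays labelled BTG1 shRNA, and SLC7A11 stood at 2.99 and 2.73 in that order. Histone (median -0.64, 4.13e-07), G2/M (-0.73, 9.71e-06), MLL-fusion (-0.52, 0.00797) and myeloid marker genes (0.46, 0.0392) had 0 members passing singly or adjusted over the list alone. The adjusted p with an estimated correlation was 0.623, 0.623, 0.623 and 0.631. The MLL-fusion and myeloid calls ended without the first control vehicle array (adjusted p = 0.187 and 0.233) or the second control prednisolone array (adjusted p = 0.0617 and 0.0789). The myeloid call also ended without the second vehicle array (adjusted p = 0.0844) or the first prednisolone array (adjusted p = 0.0966) labelled BTG1 shRNA, and after quantile normalization (adjusted p = 0.0786).

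**Figure D3:**
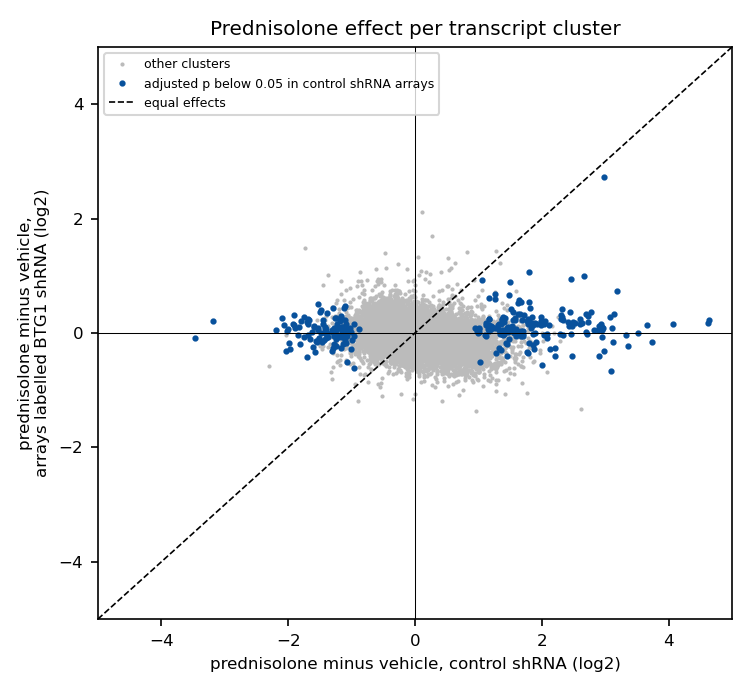
Prednisolone minus vehicle (log2) per transcript cluster in control shRNA arrays (horizontal axis) and in arrays labelled BTG1 shRNA (vertical axis); blue points are the 271 clusters with adjusted p below 0.05 in control shRNA arrays and the dashed line marks equal effects. Most blue points lie near 0 on the vertical axis, with a median of 0.11 for the rises and 0.04 for the falls.

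The 166 rises called in control cells had a median of 1.78 there and 0.11 on the arrays labelled BTG1 shRNA. The 105 falls had medians of -1.38 and 0.04. Of these 271 clusters 161 kept the sign and 2 differed by over 2-fold on the arrays labelled BTG1 shRNA, in comparisons that shared no array. Selection on the control arrays favours large control effects. Clusters were therefore also selected on the prednisolone effect averaged over both shRNAs, which gave 62 called clusters (55 higher, 7 lower) and 50 of these over 2-fold. Over these 50 clusters the effect on the arrays labelled BTG1 shRNA was 0.111 times that in control cells (0.0843 to 0.138 over 16 combinations of single arrays). Of these, 49 of 50 had the smaller effect there. This ratio rests on the selection. Over clusters above 2-fold in control cells alone it was -0.048. Over clusters called in control cells with a vehicle mean of at least 6 in both groups, a set of 106 chosen after seeing the data, it was 0.0118. It was 0.0664 without the second prednisolone array labelled BTG1 shRNA, and 0 clusters were selected without either vehicle array so labelled. The group test of the difference gave camera p = 7.36e-64 for the rises and 2.81e-12 for the falls, with p = 0.000995 and 0.00426 when the correlation was estimated. The clusters were selected on the same arrays with the same spread estimate, so these p-values are no independent support. Averaged over both shRNAs, SLC7A11 (2.86, SE 0.27), TSC22D3 (1.83, SE 0.12), DDIT4, an inhibitor of mTOR signalling (1.70, SE 0.20), KLF7 (1.35, SE 0.13), the BTG1 cluster (0.97, SE 0.14) and ID3 (-1.18) passed. VEGFA passed as well (1.12), with the larger effect on the arrays labelled BTG1 shRNA (0.82 in control cells and 1.42 there). Among the other genes named, apart from SLC7A11 (2.99 in control cells and 2.73 on the arrays labelled BTG1 shRNA), the control cells carried most of each average. The values were 2.67 and 0.99 for TSC22D3, 2.46 and 0.94 for DDIT4, 2.53 and 0.17 for KLF7, 1.26 and 0.68 for the BTG1 cluster, and -2.04 and -0.32 for ID3. The 62 calls dropped to 0 without either vehicle array labelled BTG1 shRNA and to 4 and 5 without the first and second prednisolone arrays so labelled. They dropped to 24 and 8 without the first and second control prednisolone arrays. Averaged over both treatments, 2516 clusters were higher and 1742 lower on the arrays labelled BTG1 shRNA, with CD3D at 7.96 (SE 0.12), CD74 at -7.49 (SE 0.14) and NR3C1 at -3.02 (SE 0.19).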

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

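The tests of explanations given here were chosen after the result was seen, except the test of a compressed array scale, which was set before its result was known. The spread conditions on this test and on that of lower marker expression were added afterwards, and the test of responding genes at the array floor was reworded after a related value was seen.

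The prednisolone effect differed between the arrays labelled BTG1 shRNA and the control arrays, by a test of the difference itself, for 24 clusters. The difference was 3.41 for IL1B, 3.38 for PRICKLE1, 2.36 for PDGFRB, 2.24 for PLAUR and 2.23 for GNAZ. For IL1B, PRICKLE1 and PDGFRB this is no evidence of a lost response, since these were already dim on the vehicle arrays labelled BTG1 shRNA (3.23, 3.53 and 4.07), below their control level with prednisolone, and a fall might not be measurable there. The difference was -4.42 for SGK1, -3.92 for P2RY14, -3.90 for RASSF4, -3.76 for SLA, -3.52 for NDRG2, -3.02 for GSDME, -2.89 for CEMIP2, -2.84 for RIN2, -2.77 for SMIM3, -2.56 for TXNIP, -2.46 for PIK3IP1 and -2.36 for WDR91. By list, the median difference was -0.53 for general and -1.02 for lymphoid glucocorticoid-induced genes, -0.73 for G2/M genes, 0.81 for cholesterol synthesis, -0.32 for FOXO targets, -0.52 for MLL-fusion genes, -0.64 for histones and 0.46 for myeloid markers. Camera called these 8 lists with the preset correlation and 0 of them with an estimated one (adjusted p = 0.0714 to 0.631 with an estimated correlation). Fry called 4 of them: both glucocorticoid lists, FOXO targets and cholesterol synthesis. Of the clusters, 0 passed without the second control prednisolone array or without any single array labelled BTG1 shRNA, 15 without the second control vehicle array and 7 without the first control prednisolone array.

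The arrays labelled BTG1 shRNA carried CD3D, CD3E and CD3G at or above the 99.0th percentile, with CD3G at 11.60 and CD3D at 11.47 under vehicle, while 1 of the 11 measured T-cell markers, a list that shares 0 genes with the others, reached a level of 6 in control vehicle arrays. A mixture that still held at least 10% RNA of the control-type cells is argued against by 12 of the 21 B-lineage genes, which lay below that share of their control level by more than 2 standard errors, and array scaling by a median CD3 difference of 8.17 after quantile normalization. Of 34 splits of the arrays 1, the real one, gave as many called clusters (3890, highest other 1). Every other split leaves the shRNA difference in the spread, so few calls there were largely fixed in advance. The arrays of a label may also share a culture, so the splits cannot exclude chance between cultures. RNA of another cell line, of T lineage, on these arrays is a candidate explanation, but the CD3 levels that raised it cannot also test it, and the labels name no sorting step. It and an effect of the BTG1 shRNA itself in RS4;11 cells cannot be told apart, because the BTG1 cluster difference of -2.06 is what a knockdown and another line both allow and shRNA and lineage coincide on all arrays.

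Over the 50 clusters selected for it, the response to prednisolone was smaller on the arrays labelled BTG1 shRNA, with a slope of 0.111. This did not hold in every list. The median for amino acid response genes was 0.55 in control cells and 0.53 on those arrays. For cholesterol synthesis genes it was -0.20 and 0.64 (camera adjusted p of the difference 0.000201, 0.142 with an estimated correlation). Noise that hides a response of equal size is argued against by the highest of 16 slopes from single arrays, 0.138. Responding genes at the array floor are argued against by the highest single-array slope of 0.0382 over the 106 clusters called in control cells and at least 6 in both groups. This selection favours large control effects. Over 7 clusters selected on the averaged effect and at least 6 in both groups, the slope was 0.108 (0.0364 to 0.180 over single arrays). Less glucocorticoid receptor in another cell line and an effect of the BTG1 shRNA cannot be told apart, because NR3C1 was already lower under vehicle by -2.53 and the design confounds both. A smaller response through loss of BTG1, the biological explanation the design names, stays open and untested.

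Myeloid, erythroid and stromal marker lists, 35 clusters with a median level of 4.38, had a median difference of -0.36 with prednisolone in control shRNA cells, where camera called the myeloid list (adjusted p = 0.0453, adjusted p = 0.756 with an estimated correlation) but not the erythroid (adjusted p = 0.326) or stromal list (adjusted p = 0.073). Against the second vehicle array alone the difference was -0.0434 (0.06 and -0.13 for the single prednisolone arrays), and against the first it was -0.59 and -0.84. Lower expression with prednisolone and a compressed scale of the first vehicle array cannot be told apart, since the values rest on single arrays and dim clusters (SD 0.41 over array pairs) and quantile normalization left -0.28 (SD 0.31). The value of -0.28 lay past the bound set in advance against a compressed scale, but by less than its spread, a condition added after the value was seen, and no biological explanation beyond prednisolone was tested.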

How the results depend on the processing

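The alternatives with the first control vehicle array left out and quantile normalization, with a floor of 6 for the slope, and with clusters of several symbols as list members were chosen after the result was seen; all others were planned. Signal over background was not given, so dim clusters are limited by the array floor. The cause of the changes listed here was not tested, apart from what follows by construction. Stricter thresholds call fewer clusters. The list test with an estimated correlation has fewer degrees of freedom. Leaving out an array of a group outside a contrast changes the spread estimate and its degrees of freedom, but not the effect.

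Called clusters for prednisolone in control cells (271) numbered 755 with the replicate block, 93 with array weights, 16 in the fit on the compared arrays only, 74 at adjusted p 0.01, 140 with the first control vehicle array left out and quantile normalization, and 40 to 770 with single arrays left out; 214 of the 271 were shared after quantile normalization and 177 after centring. On the arrays labelled BTG1 shRNA limma called 0 clusters under every alternative run (186 at unadjusted p below 0.05). The difference of effects (24) gave 96 with the block, 14 with centring, 50 without dim clusters, 39 with a robust trend, 11 with weights, 4 at adjusted p 0.01 and 0 to 24 with single arrays left out. The shRNA contrast under vehicle (2623) gave 4553 with the block, 1472 at adjusted p 0.01 and 1289 to 5958 with single arrays left out, and under prednisolone (3134) 1863 at adjusted p 0.01 and 1746 to 3891. Averaged prednisolone (62) gave 126 with the block, 9 at adjusted p 0.01 and 0 to 46, and averaged shRNA (4258) 2269 with over 2-fold required, 2768 at adjusted p 0.01 and 3008 to 5239. The replicate numbers share no stated batch. Deviations of same-numbered arrays correlated at 0.00722 between control prednisolone and BTG1 shRNA vehicle. In the other pairs of groups they correlated at 0.263 to 0.593, so a factor shared by number stays possible.

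Clusters over 2-fold in control cells (940) were 3331 at 1.5-fold, 530 in both same-numbered pairs and 556 to 2672 with single arrays left out; on the arrays labelled BTG1 shRNA (38) 370, 8 and 33 to 280. The slope (0.111) reversed to -0.048 with selection in control cells alone and to -0.126 with selection on control pair 2, and was 0.0598 with selection on the arrays labelled BTG1 shRNA, 0.0313 with selection on control pair 1, 0.0831 with the block and 0.0664 to 0.134 with single arrays left out, without a value when either vehicle array labelled BTG1 shRNA was left out (0 clusters selected). Over 7 clusters at least 6 in both groups it was 0.108.

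Called lists with an estimated correlation were 1, 2, 0, 0 and 0 (10, 12, 8, 5 and 14 with the preset), in the order prednisolone in control cells, on the arrays labelled BTG1 shRNA, their difference, shRNA under vehicle and under prednisolone. Fry called 2 lists in the second, 4 in the third and 12 in the fourth. With single arrays left out the ranges were 10 to 12, 6 to 14, 8 to 13, 5 to 11 and 12 to 14. On the arrays labelled BTG1 shRNA, RNA interference genes (adjusted p = 0.849, range with single arrays left out 0.00309 to 0.849) and histones (0.0868, range 6.93e-28 to 0.0868) reversed without prednisolone replicate 1. Only lists called in the main fit were followed singly, so gained list calls could not appear in the next counts. Of 392 list values with an array left out 354 kept their call, 36 lost it and 2 reversed, and of 245 under other settings 166 kept and 79 lost it. For named genes and list examples, 4693 of 5112 values kept their side of the threshold with an array left out (370 lost, 49 gained) and 5295 of 5588 under other settings (167 lost, 126 gained), with 0 reversed.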

Other observations

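The list results given first were planned, and the test of splits was set before its result was known; no test in this part was chosen after the result was seen.

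In control shRNA cells several pathways fixed in advance were not called by camera with prednisolone. Without the first control vehicle array, camera called more lists lower and fewer higher. Some of the missing calls given here therefore depend on that array. Among pro-apoptotic BCL2 relatives 0 of 10 passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.408), where the median of -0.18 and the mean of 0.12 differ in sign and the test leaned up. PMAIP1, which encodes NOXA, stood at 1.40 (SE 0.40, adjusted p = 0.176) and BID at -0.64 (SE 0.19, adjusted p = 0.191). Of the anti-apoptotic relatives 4 were measured, too few to test, with BCL2L1 at -0.57 (SE 0.21, adjusted p = 0.294). Oxidative phosphorylation genes had a median of -0.06, a mean of 0.02 and a median of 0.06 after centring (camera adjusted p = 0.601). G1/S and DNA replication genes had a median of -0.02, which centring turned to 0.11 (camera adjusted p = 0.979). Glycolysis and cholesterol synthesis genes had medians of -0.17 and -0.20 (camera adjusted p = 0.122 and 0.707). Interferon response genes had a median of -0.15 and a mean of -0.08 while camera leaned up (adjusted p = 0.979). Fry, which does not compare a list with other genes, called them lower (adjusted p = 0.0496). The receptor with its chaperones and coregulators had a median of -0.37 with 4 of 13 lower adjusted over the list alone (camera adjusted p = 0.573). Unfolded protein response genes had a median of -0.23 (camera adjusted p = 0.557) with the chaperone HSPA5 at -1.21 (SE 0.23, adjusted p = 0.0557), and heat shock genes -0.46 (camera adjusted p = 0.143) with HSPB1 at -1.05 (SE 0.25, adjusted p = 0.112). NF-kB targets had a median of -0.40 (camera adjusted p = 0.326), where NFKBIA rose by 2.04 and CD83 stood at -0.59 (SE 0.18, adjusted p = 0.208). Immediate early genes had a median of -0.40 (camera adjusted p = 0.166), with a fall of IER2 (-1.49, SE 0.26, adjusted p = 0.0433) that was lost without any array but the second control vehicle array (adjusted p = 0.0541 to 0.366). Erythroid and platelet markers had a median of -0.36 (camera adjusted p = 0.326) and stromal and epithelial markers -0.37 (camera adjusted p = 0.073), of which PDGFRB fell.

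B-lineage genes had a median of -0.21 with prednisolone in control cells (camera adjusted p = 0.121), yet 3 of 21 fell singly and 5 fell and 1 rose adjusted over the list alone. These were the inhibitory receptor CD22 (-1.59, SE 0.21, adjusted p = 0.0142), the transcription factor SPIB (-1.71, SE 0.24, adjusted p = 0.0181) and the adaptor BLNK (-1.53, SE 0.27, adjusted p = 0.0446), and all missed the threshold without the second control prednisolone array (adjusted p = 0.151, 0.175 and 0.315). BLNK missed it as well without any array but the first control vehicle array, CD22 without the first control prednisolone array and SPIB without either vehicle array labelled BTG1 shRNA (adjusted p = 0.0507 to 0.121). In the antigen presentation list the peptide transporter TAP1 rose by 1.16 (SE 0.21, adjusted p = 0.0491), a call lost without any 1 of the 8 arrays (adjusted p = 0.0525 to 0.412). Where an array labelled BTG1 shRNA was left out, only the spread estimate behind these calls changed, not the effects. Clusters over 2-fold with prednisolone in both shRNA groups numbered 10, of which 4 moved in the same direction, against 2.00 expected for independent lists.

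The prednisolone calls averaged over both shRNAs were set against other splits of the 8 arrays, each fitted beside the shRNA label. The real split gave 0 called clusters in this additive model and the highest of the others gave 0. All 34 of 34 splits then gave as many by construction, so the comparison says nothing about chance. With 4 group means the same contrast gave 62.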
